A study of Arabidopsis thaliana with 18 samples.

How the data were processed

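RNA was measured by sequencing in 18 Arabidopsis thaliana root libraries, 3 from each of 6 genotypes. The genotypes were the wild type Col-0 (WT), rab8d-2, gun1-101, nac103-11, and the double mutants nac103-11 rab8d-2 and gun1-101 rab8d-2. Per the labels, total RNA was prepared from root tips of seedlings grown on half-strength medium with sucrose in long days, and mRNA libraries were sequenced on a BGI platform. The sample titles give an age of 4 days and the series design gives 3 days, so the age is uncertain by 1 day. Strandedness is not stated and was not needed for a table of counts.

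The authors made the expected counts per gene (unit expected_counts), which are estimated counts of reads, with RSEM 1.3.1 on the TAIR10 build, and the deposited table holds them for each library without normalization. A second set of columns holds the authors' TPM values (unit tpm), which summed to between 67.1% and 79.5% of their nominal total per library. The table covers a part of the annotation, and whether that accounts for the shortfall was not tested. The 12 deposited columns of genotype means equalled the means of the 3 libraries within a tolerance of 1e-06 and were not used. The table has 25177 genes, all matched by gene ID to RefSeq, where all are protein coding. No gene of the plastid or mitochondrial genome is in it. Symbols came from the table, except 22 that were stored there as dates and were taken from RefSeq. For 329 genes that share a symbol the locus tag was used. In the expected counts, 19.6% of values were off a whole number by more than the same tolerance, and all were rounded. Total counts lay between 22625981 and 23090995 per library. A count of 0 in the 3 libraries of a genotype allows up to 3 counts, or 0.0387 to 0.0487 CPM (counts scaled to the library total) depending on the genotype. Intervals of ratios with 1 to 3 counts are 95% exact binomial intervals (Clopper-Pearson). Such intervals and floors cover counting error only.

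Genes were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr kept 21004 genes and removed 4173, library sizes were scaled by TMM (factors 0.706 to 1.17), dispersions were estimated with estimateDisp (common dispersion 0.104), and a robust quasi-likelihood model with 1 term per genotype was fitted to all 18 libraries. Each of 10 contrasts was tested with glmQLFTest, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. CPM values are TMM-scaled means with their SD over n = 3 libraries. The SE of a log2 fold change was derived from the test, as its absolute value over the square root of the quasi-likelihood F. The contrasts were each of rab8d-2, gun1-101 and nac103-11 against WT, each double mutant against rab8d-2 and against its gun1-101 or nac103-11 parent, the interaction of each double mutant, and the double mutants against each other. An interaction is the rab8d-2 effect in the gun1-101 or nac103-11 background minus the rab8d-2 effect in WT. From these contrasts came 3 derived values: the slope through 0 of the rab8d-2 effect in each double mutant on the effect in WT, over genes called in rab8d-2 against WT, and the number of genes called in the same direction in both double mutants against rab8d-2. The SE of a slope is a jackknife over the 12 libraries it uses.

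Gene lists, 27 in number with 508 members, were fixed before the data were examined, as were the contrasts, the tests, the alternative analyses named first below and the rule for named genes. Members were matched by locus and symbol, which left 406. The 2 lists of plastid-encoded genes had no member in the table and are not analysed here, and 25 lists were tested. They cover photosynthesis, tetrapyrrole synthesis and plastid signalling, plastid chaperones and proteases, plastid translation, DNA damage, CDK inhibitors, S phase, G2 and M phase, root meristem regulators, the unfolded protein response, mitochondrial dysfunction, oxidative stress and detoxification, auxin, cytokinin, abscisic acid, jasmonate and salicylate, flavonoid synthesis, iron deficiency, phosphate starvation, and markers of columella and root cap, root hair, endodermis, xylem, phloem, and non-hair epidermis and cortex. List tests used camera (limma 3.58.1) on the edgeR fit with a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Estimated correlations and fry were alternatives. A fry p tests whether the genes of a list move on balance in one direction and does not compare the list with other genes. Member counts are over all genes tested unless given as adjusted over the list alone. The text names the 3 mutated genes, the 10 highest and 10 lowest log2 fold changes per contrast among called genes with a symbol, at least 5 CPM in the higher genotype and no overlap of libraries (overlap not asked of interactions), and up to 3 called members per list or the member with the smallest p.

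Alternative analyses set before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-trend on log2(TPM + 1), no filter on low counts, a minimum of 2-fold, a fit of the contrast's own libraries, a replicate block, and each library left out in turn. After the data were seen, 5 alternatives were added: leaving out WT replicate 3 and nac103-11 rab8d-2 replicate 3 together, summing gun1-101 rab8d-2 replicates 1 and 2, a clock score or a seed storage score as a covariate, and removal of a trend with exon length in each library. Another 6 gene groups were also added then: aliphatic glucosinolate synthesis, morning clock, evening clock, seed storage, heat shock, and early wound or touch genes. The replicate numbers were checked as possible pairs: 20 of the 45 same-number pairs of libraries correlated below 0 after genotype means were removed, and 8 of 18 libraries correlated best with a library of their own number, so the numbers were not read as pairs, although the 3 same-number pairs of gun1-101 with gun1-101 rab8d-2 correlated at 0.191 to 0.275. The steps were tested on simulated data with 50 changed genes per fold: edgeR recovered 10% at 2-fold and 80% at 4-fold with 1 unchanged gene called, and the DESeq2 Wald test 36% and 92% with 30 unchanged genes called. Other splits of the libraries were run for each contrast and derived value, with slopes over the 2585 genes of lowest p in each split. No sample was left out of the reported values.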

Results

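The series asks what GUN1 and NAC103 do in the root of rab8d-2, a mutant of a plastid translation elongation factor. GUN1 is a plastid protein of plastid-to-nucleus signalling, and NAC103 is a transcription factor linked to the unfolded protein response and to DNA damage signalling. Expression was measured by RNA sequencing in root tips of 6 genotypes with 3 libraries each: WT, rab8d-2, gun1-101, nac103-11, and the double mutants nac103-11 rab8d-2 and gun1-101 rab8d-2. The labels call the libraries biological replicates and do not say whether they came from separate cultures. Total counts were 22625981 to 23090995 per library, and 21004 genes were tested. WT replicate 3 and nac103-11 rab8d-2 replicate 3 stood apart from the other libraries of their genotypes. Scaling by TPM moved the median log2 fold change of all genes by 0.25 in rab8d-2 against WT, 0.16 in gun1-101 and 0.12 in nac103-11 against WT, 0.19 in gun1-101 rab8d-2 against gun1-101, and -0.16 in nac103-11 rab8d-2 against rab8d-2. That shift was -0.28 for the interaction of nac103-11 and rab8d-2 and 0.26 between the double mutants. Fold changes below are TMM-scaled, with medians over all genes between -0.05 and 0.09.

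RAB8D, listed under the symbol RABE1b (AT4G20360), had 137 ± 34.9 CPM in WT and 13.7 ± 4.53 CPM in rab8d-2 (SD, n = 3), a 10.0-fold lower level (log2 -3.33 ± 0.34 SE, adjusted p = 6.57e-05). It also fell in gun1-101 rab8d-2 against gun1-101 (log2 -3.72, adjusted p = 1.34e-05) and in nac103-11 rab8d-2 against nac103-11 (log2 -3.52, adjusted p = 4.05e-05). NAC103 (AT5G64060) rose from 1.07 ± 0.797 CPM in WT to 19.6 ± 9.29 CPM in rab8d-2, 18.2-fold (log2 4.18 ± 0.52, adjusted p = 0.000439). Its level was 14.4 ± 2.94 CPM in gun1-101 rab8d-2 and 6.24 ± 2.66 CPM in nac103-11 rab8d-2, where reads from the gene were thus still present. Against rab8d-2, NAC103 did not pass in either double mutant (log2 -0.44, adjusted p = 0.595 and log2 -1.65, adjusted p = 0.061). GUN1 (AT2G31400) had 147 ± 16.7 CPM in WT and 79.6 ± 11.7 CPM in gun1-101, which did not pass (log2 -0.89, adjusted p = 0.171). It fell from 108 ± 14.7 CPM in rab8d-2 to 54.1 ± 5.57 CPM in gun1-101 rab8d-2 (log2 -0.995, adjusted p = 0.00621), and from 130 ± 25.6 CPM in nac103-11 to 74.8 ± 2.81 CPM in nac103-11 rab8d-2 (log2 -0.80, adjusted p = 0.00351). GUN1 fell in gun1-101 rab8d-2 against gun1-101 as well (log2 -0.56, adjusted p = 0.0241). NAC103 rose in each double mutant against its parent, by log2 4.61 ± 0.54 in gun1-101 rab8d-2 (adjusted p = 7.86e-05) and by log2 5.47 ± 0.62 in nac103-11 rab8d-2 (adjusted p = 9.03e-05). In nac103-11 itself NAC103 had 0.136 ± 0.0507 CPM, with 2 to 4 counts per library, so the second rise rests on few counts. Against WT it did not pass there (log2 -2.94, adjusted p = 0.565). RNA of GUN1 and NAC103 was thus present in the mutants, and whether protein was made is not known from these data. In the fit of the 6 libraries alone, the rise of NAC103 in rab8d-2 against WT was as large (log2 4.21) and was not called.

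**Figure D1:**
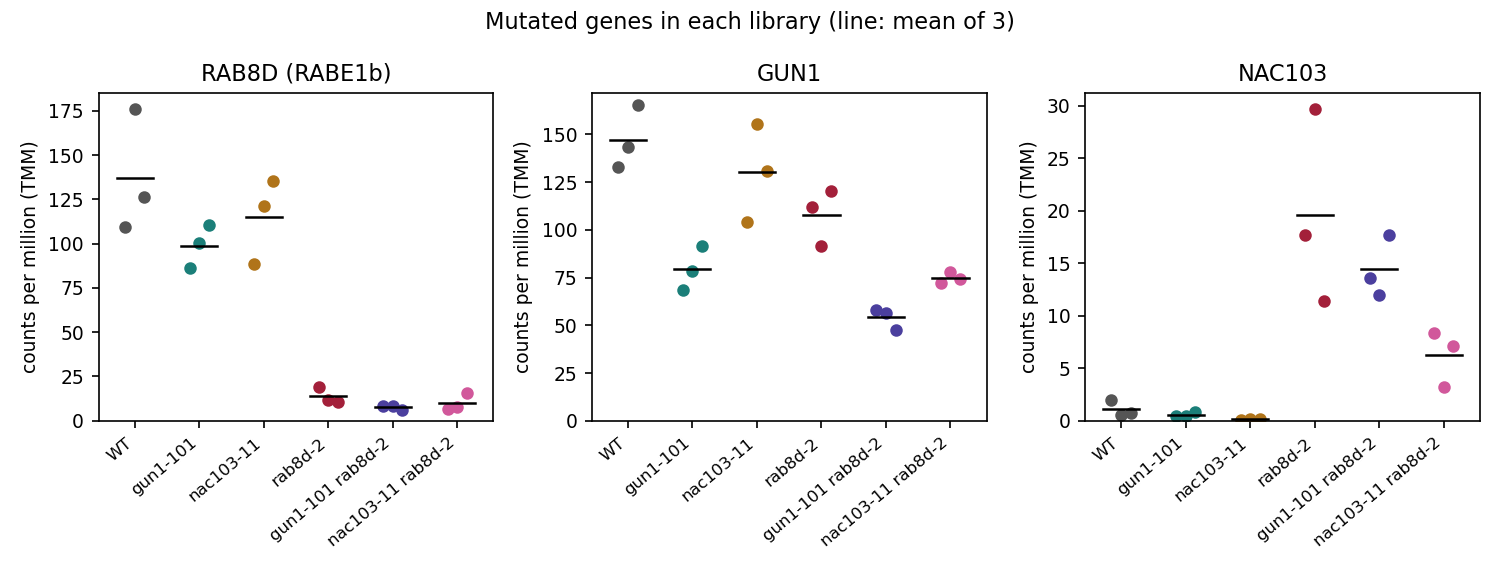
TMM-scaled CPM (y axis, from 0) of RAB8D, GUN1 and NAC103 in each genotype (x axis), with 1 point per library and a line at the mean of 3. RAB8D averaged 137 CPM in WT and 13.7 CPM in rab8d-2, and NAC103 averaged 1.07 CPM in WT and 19.6 CPM in rab8d-2.

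In rab8d-2 against WT, ACC2, EMB1030, NDB4 and NAC044 were among the 10 highest rises by the rule for named genes. ACC2 (AT1G36180), which encodes a plastid acetyl-CoA carboxylase, rose 25.7-fold from 4.49 ± 2.26 to 116 ± 31.2 CPM (SD, n = 3; adjusted p = 1.80e-05). EMB1030 (AT5G22800), an organellar alanyl-tRNA synthetase, rose from 4.95 ± 2.47 to 108 ± 39.3 CPM (log2 4.44 ± 0.42). NDB4 (AT2G20800), an alternative NADH dehydrogenase of mitochondria, rose by log2 5.17 ± 0.36 (adjusted p = 3.30e-06). NAC044 (AT3G01600), a transcription factor of the arrest after DNA damage, rose from 0.851 ± 0.475 to 16.8 ± 1.42 CPM (log2 4.30 ± 0.46). Among the 10 lowest by the same rule, which asks for a symbol, were MRD1 (AT1G53480, log2 -7.33 ± 0.71), FRO5 (AT5G23990), a metal reductase (log2 -5.84 ± 0.97), and the sugar transporter gene SWEET3 (AT5G53190, log2 -3.69 ± 0.51). MRD1 was low in some lines whatever their RAB8D allele, as given under the single mutants.

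In the fixed lists of rab8d-2 against WT, DNA damage genes and some cell cycle genes rose, and markers of root hairs, endodermis and xylem fell. Of 28 DNA damage response genes 13 rose and none fell (16 rose adjusted over the list alone), with a median log2 fold change of 0.99. Among them were GMI1 (AT5G24280), which acts in recombination (25.8 ± 2.79 against 2.81 ± 0.997 CPM, log2 3.19 ± 0.30), and the checkpoint gene ATRAD17 (log2 2.12 ± 0.31). This list was called by camera (adjusted p = 1.29e-11; adjusted p = 0.318 with an estimated correlation). Of 27 S phase genes 3 rose (6 adjusted over the list alone; adjusted p = 1.77e-05, and 0.417 with an estimated correlation), and of 27 G2 and M phase genes 2 rose (0 over the list alone; adjusted p = 0.00157, and 0.654 with an estimated correlation). With a trend with exon length removed in each library, 6 and 3 of them rose. AIL6 (PLT3), a root stem cell regulator, rose by log2 1.59 ± 0.29 and was 1 of 3 of the 26 meristem regulators that rose, while 1 fell (5 and 3 over the list alone).

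Root hair markers fell in 8 of 10 members (8 adjusted over the list alone; median log2 -2.36), and endodermis and Casparian strip markers fell in 8 of 10 (9 lower and 1 higher over the list alone; median -1.71). Among xylem markers 8 of 11 fell (10 over the list alone; median -1.89), and among phloem markers 3 of 7 (3 over the list alone). CASP5, a scaffold protein of the Casparian strip, had 23.3 ± 10.7 CPM against 79.6 ± 6.41 in WT (log2 -1.77 ± 0.38). CESA4 (IRX5), a cellulose synthase of secondary walls, fell by log2 -1.63 ± 0.33, and LAC17, a laccase of lignin formation, by log2 -2.39 ± 0.48. Camera called these lists at adjusted p = 6.74e-06, 1.05e-05, 3.57e-07 and 0.0269, and with an estimated correlation the adjusted p was 0.318 for the first 3 and 0.475 for phloem. Without rab8d-2 replicate 2 the calls of CASP5, CESA4 and LAC17 ended, at log2 -1.46, -1.43 and -2.13. Columella and root cap markers did not pass in any of 8 members, and 1 of 4 non-hair epidermis and cortex markers rose. A dissected root tip can hold these cell types in different shares, which was not separated from a change within cells.

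Among nutrient and hormone lists, 3 of 12 iron deficiency genes fell (5 over the list alone; adjusted p = 0.00182, and 0.318 with an estimated correlation), including the transcription factor gene bHLH39 (log2 -3.15 ± 0.57). For bHLH38, with 2 counts in rab8d-2 and 70 in WT, WT exceeded rab8d-2 by a ratio of 41.8 (95% counting interval 11.2 to 352). Of 8 phosphate starvation genes 2 fell (4 over the list alone; adjusted p = 0.00852, and 0.318 with an estimated correlation). Among 11 CDK inhibitors 1 rose and 1 fell (1 and 1 over the list alone; median log2 0.06), and of 15 auxin response genes 2 fell (2 higher and 2 lower over the list alone; median -0.15), with neither list called. CRF2, a cytokinin response factor, rose (log2 0.95 ± 0.16) and CKX4, a cytokinin oxidase, fell (log2 -2.09 ± 0.39), 1 member each way of 12. In the mitochondrial dysfunction list 3 of 11 rose and 1 fell (4 and 1 over the list alone; adjusted p = 0.0205, and 0.475 with an estimated correlation). None of 30 photosynthesis genes passed (0 over the list alone), although the list was called lower at a median of -1.08 (adjusted p = 0.00273, and 0.775 with an estimated correlation), and its mean log2 CPM in the WT libraries ranged from 2.23 to 5.95. Of 20 tetrapyrrole genes 3 fell (3 over the list alone; adjusted p = 0.0259, and 0.604 with an estimated correlation), among them GLK2, a regulator of chloroplast genes (log2 -2.55 ± 0.43), and the heme oxygenase gene TED4 (log2 -1.31 ± 0.23). None of 19 unfolded protein response genes, 15 plastid translation genes or 7 flavonoid genes passed, over all genes or over the list alone.

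edgeR called 2585 genes in rab8d-2 against WT, 1009 higher and 1576 lower, of which 1651 changed at least 2-fold. The 2 groups of libraries did not overlap for 28.4% of genes, where chance gives 10%. On TPM the split turned to 1593 higher and 1143 lower, while the DESeq2 Wald test called 4150 genes and a fit of the 6 libraries alone called 76 (47 higher, 29 lower). The count was 447 without rab8d-2 replicate 2, 748 without WT replicate 2, and 7974 (4420 higher, 3554 lower) without WT replicate 3 and nac103-11 rab8d-2 replicate 3 together, and 24 of 66 named genes that were called kept their call without each single library.

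**Figure D2:**
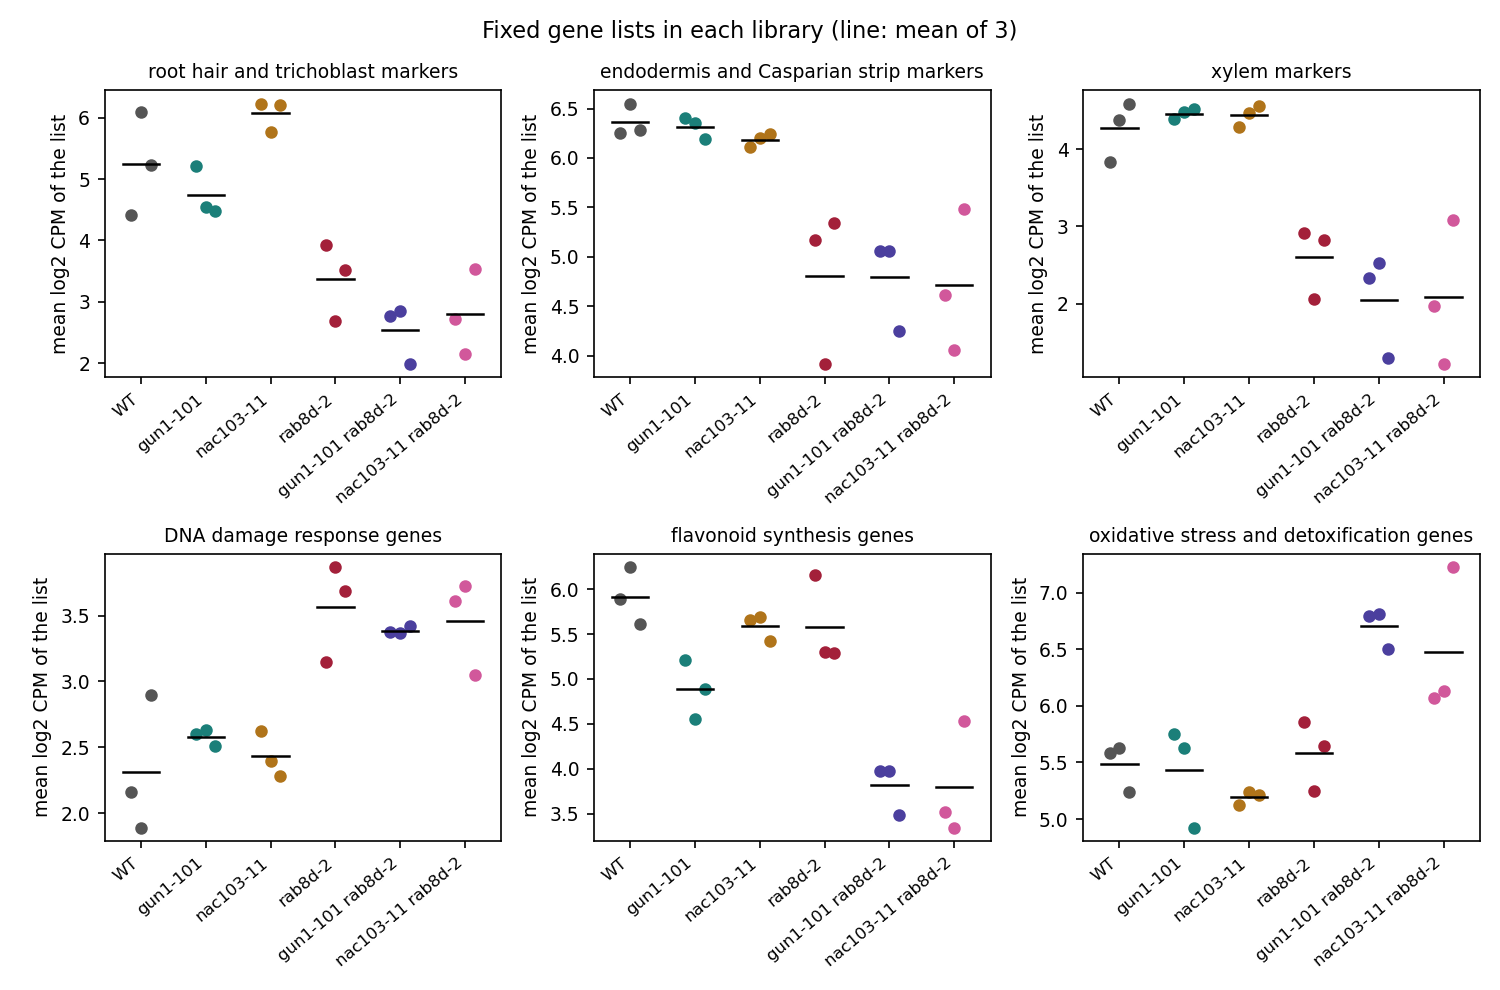
Mean log2 CPM of 6 fixed gene lists (y axes, not from 0) in each genotype (x axis), with 1 point per library and a line at the mean of 3. Root hair markers averaged 5.25 in WT and 3.38 in rab8d-2, DNA damage genes 2.31 and 3.57, and flavonoid genes 5.58 in rab8d-2 and 3.82 in gun1-101 rab8d-2.

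The single mutants gun1-101 and nac103-11 were compared with WT for the effect of each gene in roots with RAB8D. In gun1-101, 4 genes fell and none rose. MRD1 fell by log2 -6.27 ± 0.66 (0.831 ± 0.893 against 64.3 ± 22.2 CPM, n = 3; adjusted p = 0.00111). IMS2, an enzyme of methionine chain elongation in glucosinolate synthesis, fell by log2 -2.86 ± 0.39, and G6PD3, a plastid glucose-6-phosphate dehydrogenase, by log2 -1.52 ± 0.20. The calls of both ended in 4 of the 6 refits that left out 1 library, for IMS2 at log2 -2.68 without WT replicate 1, and -2.89, -2.63 and -3.08 without gun1-101 replicates 1, 2 and 3. For G6PD3 they ended at log2 -1.46 without WT replicate 2, and -1.54, -1.47 and -1.53 without the same 3 libraries. AT4G29200, named after its values were seen, had 0 counts in gun1-101 and 4097 in WT, at least 1506-fold lower. In nac103-11 it also had 0 counts, at least 1482-fold lower, and AT1G75945, named after its values were seen too, rose from 0.138 to 17.2 CPM.

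Of the fixed lists in gun1-101 against WT, no member passed over all genes. The list of 7 flavonoid genes had a median of -0.86, with 5 lower adjusted over the list alone, and was called (adjusted p = 2.77e-07; adjusted p = 0.160 with an estimated correlation). FLS1, flavonol synthase, had log2 -1.84 ± 0.44 (adjusted p = 0.371). Plastid translation and phosphate starvation genes were called lower (adjusted p = 0.00276 and 0.00391, and 0.921 and 0.160 with an estimated correlation), and cytokinin and abscisic acid response genes higher (adjusted p = 0.0112 and 0.0205, and 0.160 and 0.921 with an estimated correlation). All 3 gun1-101 libraries had clock scores, morning minus evening genes, of 1.11 to 1.41, against -8.30, -7.28 and 2.76 in WT. In nac103-11 no member of any list passed over all genes, and 10 lists were called by camera, with an adjusted p of 0.624 to 0.667 with an estimated correlation. Among them, root hair markers were higher (median 0.66, adjusted p = 6.39e-05, 0 of 10 members over the list alone) and abscisic acid response genes lower (median -1.29, adjusted p = 0.000141, 3 of 13 lower over the list alone). DNA damage genes were called higher with a median of 0.19 and a mean of -0.17, which differ in sign.

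edgeR called 4 genes in gun1-101 and 2 in nac103-11 against WT, with 1489 and 1363 genes at an unadjusted p below 0.05. By the DESeq2 Wald test the counts were 78 and 58, and in fits of the 6 libraries alone they were 0 and 0. Without WT replicate 3 the gun1-101 count was 39, and without any 1 of the gun1-101 libraries it was 2. Without WT replicate 3 and nac103-11 rab8d-2 replicate 3 together, the counts were 3946 (2400 higher, 1546 lower) and 1219 (1026 higher, 193 lower).

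How much of the rab8d-2 response stayed in the gun1-101 or nac103-11 background was asked by comparing each double mutant with its gun1-101 or nac103-11 parent. Of the 2585 genes called in rab8d-2 against WT, 2535 (98.1%) had the same sign in gun1-101 rab8d-2 against gun1-101, and 1895 were called in the same direction (651 higher, 1244 lower) against 7 in the opposite one. In nac103-11 rab8d-2 against nac103-11, 2476 (95.8%) had the same sign, 1635 were called in the same direction (505 higher, 1130 lower) and 3 in the opposite one. The slope of the rab8d-2 effect was 0.919 ± 0.171 in gun1-101 and 0.911 ± 0.267 in nac103-11 (jackknife SE, 12 libraries). A simulation of equal effects gave 0.915 and 0.900, with 50 changed genes at each of 1.5-, 2-, 4- and 8-fold. It changed fewer genes than the 2585 called here, and those it recovered were mostly changed at 4-fold or more. Its slopes are therefore no exact reference for equal effects in the data. Leaving out single libraries gave slopes of 0.754 to 0.899 and of 0.703 to 1.02.

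**Figure D3:**
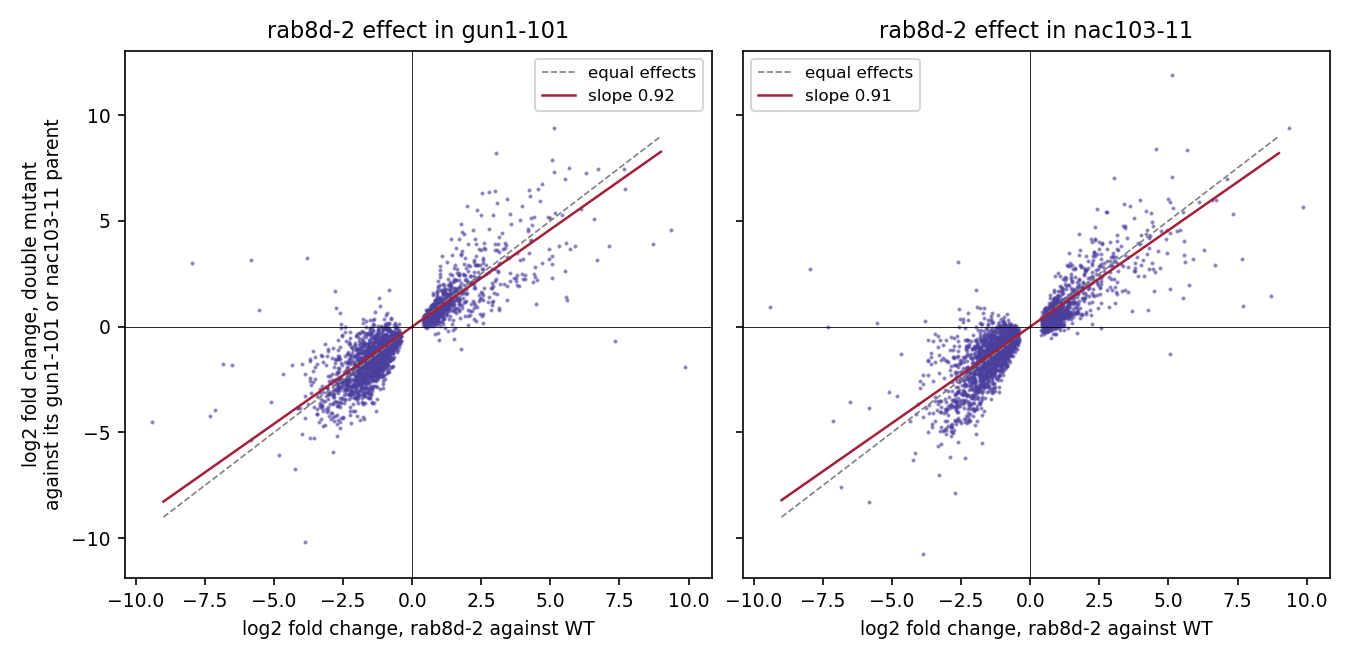
Log2 fold change of rab8d-2 against WT (x axes) and of each double mutant against its gun1-101 or nac103-11 parent (y axes), with 1 point per gene called in rab8d-2 against WT, a dashed line of equal effects and a solid line at the fitted slope through 0. The slopes were 0.92 in gun1-101 and 0.91 in nac103-11.

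In gun1-101 rab8d-2 against gun1-101, NDB4 rose by log2 5.37 ± 0.33 to 22.2 ± 0.306 CPM, NAC044 by log2 4.05 ± 0.45 and AIL6 by log2 2.19 ± 0.30 (n = 3). WOX5, the transcription factor of the quiescent centre, rose from 2.77 ± 0.647 to 14.9 ± 1.24 CPM (log2 2.43 ± 0.32). DIR5, a dirigent protein gene, had 0 counts in gun1-101 and 2200 in the double mutant, at least 643-fold higher. The water channel gene TIP2;3 fell from 603 ± 21.3 to 9.79 ± 3.27 CPM (log2 -5.94 ± 0.62). Among 28 DNA damage genes 13 rose and none fell (16 and 2 over the list alone; adjusted p = 3.52e-05), and among 27 G2 and M phase genes 8 rose (14 over the list alone and 13 over all genes with the length trend removed; adjusted p = 0.000317). Xylem markers fell in 10 of 11 members (11 over the list alone; median -2.38, adjusted p = 4.33e-08), root hair markers in 8 of 10 (median -2.71, adjusted p = 7.73e-05) and endodermis markers in 6 of 10 (8 over the list alone; median -1.42, adjusted p = 0.000543), with CASP5 at log2 -3.08 ± 0.40. Oxidative stress genes rose in 12 of 31 members and fell in 1 (adjusted p = 0.000513), mitochondrial dysfunction genes rose in 5 of 11 and fell in 1 (8 and 1 over the list alone; adjusted p = 0.000513), and unfolded protein response genes rose in 4 of 19 (adjusted p = 0.00203). With an estimated correlation the adjusted p was 0.492 for each of these lists. Of 22 plastid chaperone and protease genes 5 fell, among them FTSH1 (log2 -2.05 ± 0.27), and 1 rose. The median and mean of this list were 0.04 while camera ranked it lower, so their signs differ. Photosynthesis genes, a list set to stand for shoot tissue, fell in 5 of 30 members (adjusted p = 0.000543, and 0.554 with an estimated correlation). Over all genes, 3288 of 21004 were called lower, a like share. Flavonoid genes fell in 5 of 7 members (5 lower and 1 higher over the list alone; adjusted p = 0.00581, and 0.492 with an estimated correlation).

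edgeR called 5946 genes in gun1-101 rab8d-2 against gun1-101, 2658 higher and 3288 lower. Of all tested genes, 64.2% had no overlap of libraries, where chance gives 10%. Chance gives more than that if gun1-101 rab8d-2 replicates 1 and 2 came from 1 RNA sample, which the labels do not say. On TPM the split turned to 3553 higher and 2582 lower. The count was 3897 without gun1-101 replicate 3, 3957 without gun1-101 replicate 2, 3849 and 3863 without gun1-101 rab8d-2 replicates 1 and 2, 3908 with those last 2 summed, 9517 without WT replicate 3 and nac103-11 rab8d-2 replicate 3 together, and 10974 in a fit of the 6 libraries alone.

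In nac103-11 rab8d-2 against nac103-11, NDB4 rose by log2 5.62 ± 0.34, NAC044 by log2 4.19 ± 0.45 and GMI1 by log2 2.65 ± 0.29 (n = 3). WOX5 rose from 3.19 ± 1.06 to 12.7 ± 4.04 CPM (log2 1.99 ± 0.31). CYP715A1 had 0 counts in nac103-11 and 381 in the double mutant, at least 128-fold higher. For DIR5, with 3 counts in nac103-11 and 2981 in the double mutant, the ratio was 1000 (95% counting interval 342 to 4853). LRX1, a cell wall protein of root hairs, fell from 118 ± 24.7 to 3.69 ± 3.05 CPM (log2 -5.03 ± 0.71). Root hair markers fell in 9 of 10 members (median -3.17, adjusted p = 9.19e-10, and 0.255 with an estimated correlation), and xylem markers in 10 of 11 (median -2.22, adjusted p = 2.05e-08, and 0.255). DNA damage genes rose in 11 of 28 members (11 higher and 1 lower over the list alone; adjusted p = 8.94e-05, and 0.308 with an estimated correlation), oxidative stress genes in 14 of 31 with 1 lower (adjusted p = 1.61e-05, and 0.308), and mitochondrial dysfunction genes in 8 of 11 (9 higher and 1 lower over the list alone; adjusted p = 1.97e-05, and 0.255). Tetrapyrrole genes fell in 8 of 20 members (9 over the list alone; adjusted p = 0.000247, and 0.308 with an estimated correlation). They included GUN5, a subunit of magnesium chelatase, which fell from 32.8 ± 5.14 to 2.64 ± 1.07 CPM, and GLK2 (log2 -3.74 ± 0.46). Flavonoid genes fell in 5 of 7 members (median -2.21, adjusted p = 1.24e-05, and 0.255 with an estimated correlation) and photosynthesis genes in 8 of 30 (adjusted p = 1.24e-05, and 0.589).

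edgeR called 6086 genes in nac103-11 rab8d-2 against nac103-11, 3089 higher and 2997 lower, and 40.8% of genes had no overlap of libraries, where chance gives 10%. Of them, 3624 changed at least 2-fold, 1662 higher and 1962 lower. On TPM the split turned to 2599 higher and 3067 lower. The split turned to 2963 higher and 3916 lower without nac103-11 rab8d-2 replicate 3. The count was 4020 without nac103-11 replicate 2 and 2875 in a fit of the 6 libraries alone.

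The effect of the gun1-101 mutation in rab8d-2 was asked with gun1-101 rab8d-2 against rab8d-2. DIR5 rose from 0.137 ± 0.126 to 28.3 ± 5.37 CPM (log2 7.64 ± 1.05, n = 3), and PRX52, a peroxidase of lignin formation, from 1.01 ± 0.598 to 30.1 ± 2.40 CPM (log2 4.89 ± 0.63, adjusted p = 0.00127). The glutathione transferase genes GSTU11 (log2 3.81 ± 0.50), GSTU2 (log2 1.59 ± 0.23) and GSTU1 rose, GSTU1 by 2.83-fold from 42.3 ± 9.51 to 120 ± 5.44 CPM. They belong to the oxidative stress and detoxification list, where 6 of 31 members rose (13 higher and 1 lower over the list alone; median 0.99, adjusted p = 3.27e-09, and 0.340 with an estimated correlation). Flavonoid synthesis genes fell in 4 of 7 members (5 over the list alone; median -2.32, adjusted p = 9.46e-11, and 0.154 with an estimated correlation). TT4, chalcone synthase, fell from 642 ± 215 to 78.9 ± 22.8 CPM (log2 -3.02 ± 0.39, adjusted p = 0.00127), FLS1 by log2 -2.91 ± 0.46, TT5, chalcone isomerase, by log2 -2.74 ± 0.37, and F3H, flavanone 3-hydroxylase, from 126 ± 15.5 to 25.2 ± 6.47 CPM (log2 -2.32 ± 0.27, adjusted p = 0.000509). BIP3, a chaperone of the endoplasmic reticulum, rose by log2 4.95 ± 0.72 and was the single one of 19 unfolded protein response genes to rise. Mitochondrial dysfunction genes rose in 3 of 11 members (4 over the list alone; adjusted p = 0.000758, and 0.340 with an estimated correlation), among them NDB4 (log2 1.86 ± 0.27). Jasmonate and salicylate genes rose in 1 of 11 members (4 over the list alone; adjusted p = 0.000845, and 0.340 with an estimated correlation), and plastid translation genes fell in 2 of 15 (11 over the list alone; adjusted p = 6.29e-05, and 0.415 with an estimated correlation). Root hair markers were called lower with no member past the threshold (adjusted p = 0.0411, and 0.667 with an estimated correlation). Seed storage genes, a group chosen after the data were seen, averaged log2 CPM of 1.52 ± 3.70 in rab8d-2 and -3.10 ± 1.33 in gun1-101 rab8d-2.

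edgeR called 878 genes in gun1-101 rab8d-2 against rab8d-2, 526 higher and 352 lower, and 33.4% of genes had no overlap of libraries, where chance gives 10%. On TPM 1337 genes were called, 997 higher and 340 lower, by the DESeq2 Wald test 2018, with a replicate block 545, with a clock or a seed storage covariate 1561 and 1578, and 3285 without WT replicate 3 and nac103-11 rab8d-2 replicate 3 together. Without rab8d-2 replicate 2 the split turned to 335 higher and 494 lower. The count was 339 and 383 without rab8d-2 replicates 1 and 3, 240, 209 and 525 without gun1-101 rab8d-2 replicates 1, 2 and 3, and 234 with gun1-101 rab8d-2 replicates 1 and 2 summed, which differed from each other far less than other replicates did. Without each single library, 18 of 43 named genes that were called kept their call. If gun1-101 rab8d-2 replicates 1 and 2 came from 1 RNA sample, which the labels do not say, n is 2 where it is given as 3. Chance then gives more than 10% of genes without overlap.

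For the nac103-11 mutation in rab8d-2, nac103-11 rab8d-2 was set against rab8d-2. DIR5 (log2 8.54 ± 1.07) and PRX52 (log2 4.65 ± 0.63) rose here too, as did GSTU11 (log2 3.46 ± 0.49) and GSTU1, from 42.3 ± 9.51 to 109 ± 23.2 CPM (log2 1.37 ± 0.19, n = 3; adjusted p = 0.00391). Oxidative stress genes rose in 8 of 31 members (14 higher and 1 lower over the list alone; median 0.65, adjusted p = 2.29e-08, and 0.337 with an estimated correlation). Flavonoid genes fell in 4 of 7 members (5 over the list alone; median -2.41, adjusted p = 3.47e-12, and 0.0876 with an estimated correlation): FLS1 by log2 -2.89 ± 0.46, TT5 by log2 -2.77 ± 0.37, TT4 by log2 -2.52 ± 0.39 and F3H by log2 -2.41 ± 0.27, to 23.8 ± 9.87 CPM. 4CL3, a ligase at the entry of the flavonoid pathway, fell by log2 -2.26 ± 0.36. MRD1 rose from 0.393 ± 0.292 to 53.4 ± 15.5 CPM, near its WT level. Mitochondrial dysfunction genes rose in 2 of 11 members (adjusted p = 0.00282, and 0.530 with an estimated correlation), while 1 of 8 columella markers fell (2 over the list alone; adjusted p = 0.00282, and 0.337 with an estimated correlation). Plastid lists fell in few members: 1 of 30 photosynthesis genes (adjusted p = 2.59e-06, and 0.717 with an estimated correlation), 1 of 20 tetrapyrrole genes (adjusted p = 0.000115, and 0.502) and 2 of 15 plastid translation genes (3 over the list alone; adjusted p = 0.0138, and 0.717). Of 26 meristem regulators 3 fell and 1 rose (5 and 1 over the list alone; adjusted p = 0.0361, and 0.615 with an estimated correlation). Fold changes of this contrast correlated with exon length across genes (Spearman -0.430). With that trend removed, 3 of 31 oxidative stress genes rose, 4 of 7 flavonoid genes fell, 1 of 15 plastid translation genes fell, and no meristem regulator or columella marker was called. Seed storage genes averaged log2 CPM of -2.82 ± 3.81 in nac103-11 rab8d-2, with replicate 3 at 1.54 and the other libraries at -4.48 and -5.53.

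edgeR called 534 genes in nac103-11 rab8d-2 against rab8d-2, 270 higher and 264 lower, and 17.7% of genes had no overlap of libraries, where chance gives 10%. By the DESeq2 Wald test 2096 genes were called, with a replicate block 122, with a seed storage covariate 7258, in a fit of the 6 libraries alone 2, and with gun1-101 rab8d-2 replicates 1 and 2 summed 236. The count was 75, 839 and 45 without rab8d-2 replicates 1, 2 and 3, and 912 and 201 without nac103-11 rab8d-2 replicates 1 and 3. The even split turned to 686 higher and 226 lower without nac103-11 rab8d-2 replicate 1, and to 330 higher and 509 lower without rab8d-2 replicate 2. Of 35 named genes that were called, 11 kept their call without each single library.

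Genes that changed in the same direction in both double mutants against rab8d-2 numbered 239, 141 higher and 98 lower, and none changed in opposite directions. TT4, TT5, F3H and FLS1 were among those that fell in both, and DIR5, PRX52, GSTU1 and GSTU11 among those that rose in both. Independent lists of these sizes would share 11.2 genes. In 20 simulations without any true change, which share the rab8d-2 libraries as the contrasts do, the 878 and 534 genes of lowest p shared a mean of 131.5 genes in the same direction (116 to 150). Log2 fold changes of the contrasts correlated across genes at 0.673, against 0.506 in the simulations, while 59.5% of genes had the same sign in both contrasts against 66.6% in the simulations, and genes are not independent replicates. The rab8d-2 libraries are the control of both contrasts and cannot be divided between them, so a large part of the shared genes can come from them. The shared count was 41 and 35 without rab8d-2 replicates 1 and 3, 86, 75 and 158 without gun1-101 rab8d-2 replicates 1, 2 and 3, and 79 with gun1-101 rab8d-2 replicates 1 and 2 summed. With a replicate block it was 73, by the DESeq2 Wald test 720 and with a seed storage covariate 1193.

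Whether the rab8d-2 effect differed in the gun1-101 or nac103-11 background was tested as an interaction. For gun1-101, 41 genes passed, 38 with a higher and 3 with a lower rab8d-2 effect than in WT. IMS2 (log2 4.70 ± 0.54, adjusted p = 0.00329) and CYP79F2 (log2 5.79 ± 0.78), enzymes of aliphatic glucosinolate synthesis, were among the 38, as were the aspartate kinase gene AK3 (log2 4.46 ± 0.61) and ABO3, a WRKY transcription factor gene (log2 5.71 ± 0.79). The 3 with a lower effect, AT3G47030, AT3G21380 and AT3G44120, were named after their values were seen. No member of a fixed list passed over all genes, and camera called 9 lists. Oxidative stress genes were higher (adjusted p = 1.16e-08, 5 of 31 over the list alone, and 0.392 with an estimated correlation) and flavonoid genes lower (adjusted p = 0.00851, 3 of 7 lower and 1 higher over the list alone, and 0.638 with an estimated correlation). GSTU1 had log2 1.17 (adjusted p = 0.0853) and F3H log2 -1.63 (adjusted p = 0.0847), while WOX5 had log2 2.06 (adjusted p = 0.079). For nac103-11, 2 genes passed: MRD1 (log2 7.33 ± 0.85, adjusted p = 0.00354) and AT1G75945, named after its values were seen (log2 -6.72 ± 0.65, adjusted p = 0.000683). AT1G75945 averaged 0.138 CPM in WT and 0.132 in gun1-101, against 17.2 in nac103-11 and 28.7 in rab8d-2. It averaged 12.7 CPM in gun1-101 rab8d-2 and 34.2 in nac103-11 rab8d-2. A state of the gene that differs between lines was not separated from an interaction. Here camera called 13 lists with no member past the threshold over all genes, among them oxidative stress genes as higher (adjusted p = 6.24e-09, 12 of 31 over the list alone, and 0.247 with an estimated correlation) and flavonoid genes as lower (adjusted p = 1.84e-06, 4 of 7 over the list alone, and 0.247). F3H had log2 -2.24 (adjusted p = 0.056). Fold changes of this interaction correlated with exon length across genes (Spearman -0.492). With that trend removed 7 genes were called, among them 1 of 7 flavonoid genes, which was lower, and no oxidative stress gene, and camera was not run in that setting.

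At an unadjusted p below 0.05 there were 2108 genes for the gun1-101 interaction and 3340 for that of nac103-11, and the DESeq2 Wald test called 448 and 548, limma-trend on TPM 284 and 58. The count of 41 was 11, 13 and 16 without gun1-101 replicates 2, 1 and 3, 20 and 116 without WT replicates 1 and 3, 81 and 15 without rab8d-2 replicates 2 and 3, 18 with a replicate block, and 17, 16 and 26 without gun1-101 rab8d-2 replicates 1, 2 and 3, and the count of 2 was 72 without nac103-11 rab8d-2 replicate 1 and 5 without replicate 3. With gun1-101 rab8d-2 replicates 1 and 2 summed the gun1-101 count was 16, and in a fit of the contrast's own libraries it was 103. The split of 38 higher and 3 lower turned to 39 and 42 without rab8d-2 replicate 2, and to 88 and 28 without WT replicate 3. With a seed storage covariate the counts were 1477 for gun1-101 and 34 for nac103-11, with a clock covariate 20 and 10, and without WT replicate 3 and nac103-11 rab8d-2 replicate 3 together 748 and 8. Of the named genes that were called, 4 of 10 and 1 of 1 kept their call without each single library.

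**Figure D4:**
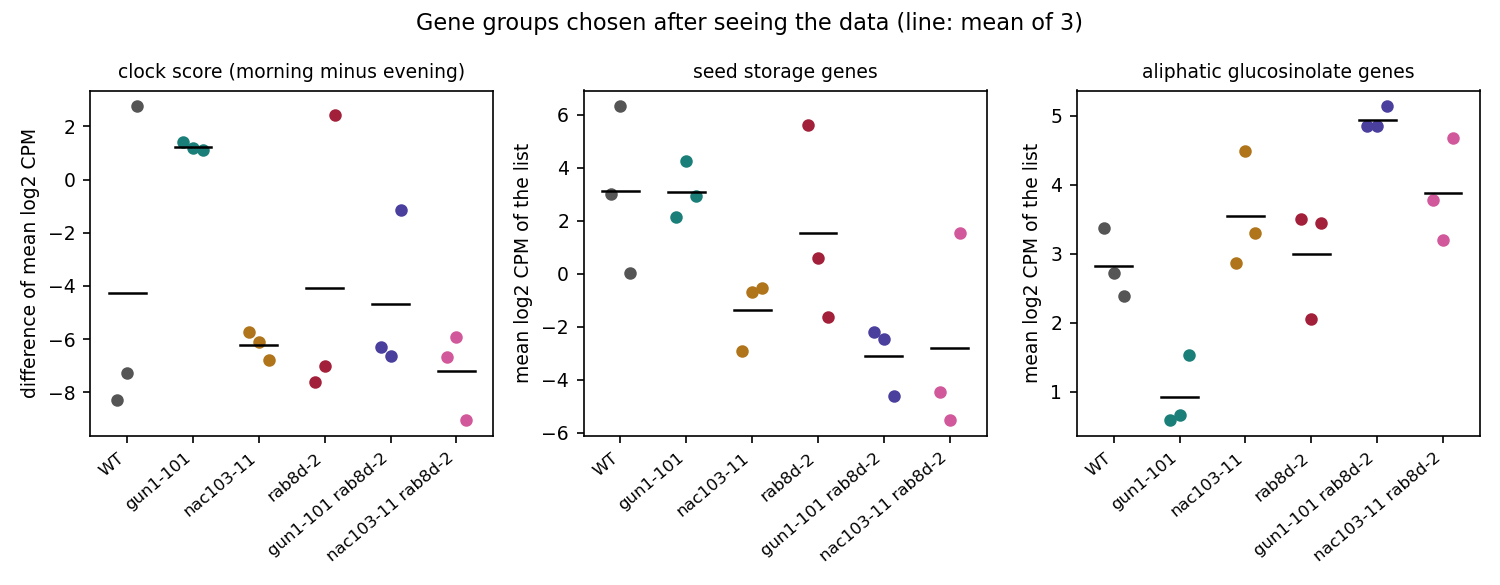
Scores of gene groups chosen after the data were seen (y axes, log2 CPM, not from 0) in each genotype (x axis), with 1 point per library and a line at the mean of 3. The clock score, morning minus evening genes, was 1.11 to 1.41 in gun1-101 and spread from -8.30 to 2.76 in WT, and the glucosinolate score averaged 0.93 in gun1-101 and 4.94 in gun1-101 rab8d-2.

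The double mutants were compared with each other for differences between the gun1-101 and nac103-11 mutations in rab8d-2. MRD1 had 3 counts in gun1-101 rab8d-2 and 3408 in nac103-11 rab8d-2, so the latter exceeded the former by a ratio of 1326 (95% counting interval 453 to 6431). SOT18, a sulfotransferase of glucosinolate synthesis, was higher in gun1-101 rab8d-2 (42.5 ± 4.87 against 11.8 ± 0.989 CPM, log2 1.84 ± 0.32, n = 3), as was AK3 (53.4 ± 8.03 against 15.2 ± 3.34 CPM). XPL1, a methyltransferase of choline synthesis, was lower (31.2 ± 1.44 against 145 ± 64.0 CPM, log2 -2.22 ± 0.40). Against rab8d-2, SOT18 was lower in nac103-11 rab8d-2 (log2 -1.29, adjusted p = 0.0452) and did not pass in gun1-101 rab8d-2 (log2 0.55, adjusted p = 0.331). SOT18 averaged 12.6 CPM in nac103-11 and 52.2 CPM in WT, which did not pass (adjusted p = 0.0904). The calls of SOT18, AK3 and XPL1 ended without gun1-101 rab8d-2 replicate 1 (log2 1.91, 1.89 and -2.18), without its replicate 2 (1.87, 1.86 and -2.22) and without nac103-11 rab8d-2 replicate 3 (1.77, 1.88 and -2.37). Of 20 tetrapyrrole genes 2 were higher in gun1-101 rab8d-2, the only list called (adjusted p = 0.0178, and 0.999 with an estimated correlation), and none was with the length trend removed. Fold changes between the double mutants correlated with exon length across genes (Spearman 0.547 over 15911 genes, which are not independent replicates).

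edgeR called 1035 genes between the double mutants, 270 higher and 765 lower in gun1-101 rab8d-2. Of all tested genes, 32.3% had no overlap of libraries, where chance gives 10%, or more if gun1-101 rab8d-2 replicates 1 and 2 were 1 RNA sample. On TPM the split turned to 605 higher and 436 lower, and with the length trend removed 35 genes were called, 26 higher and 9 lower. By the DESeq2 Wald test the count was 2611, at 2-fold 473, in a fit of the 6 libraries alone 2, with a replicate block 28, with a clock covariate 63, with a seed storage covariate 4138, with gun1-101 rab8d-2 replicates 1 and 2 summed 12, and without WT replicate 3 and nac103-11 rab8d-2 replicate 3 together 446. It was 11 and 12 without gun1-101 rab8d-2 replicates 1 and 2, and 1668, 1641 and 21 (16 higher, 5 lower) without nac103-11 rab8d-2 replicates 1, 2 and 3, and 1 of 28 named genes that were called, MRD1, kept its call without each single library.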

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

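Of the tests in this part, the count of genes beside MRD1 at an unadjusted p below 0.001 was set before its result was seen. The set rule took a count below 2 as excluding a stretch of chromosome. After the result was seen, the rule was widened to ask for a low share at 0.05 as well, which changed its outcome from excluded to open. The tests of clock phase, exon length, 1 library, the rab8d-2 effect on MRD1 and the other splits of the libraries were chosen after the results were seen.

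A difference between backgrounds drew attention to 41 genes and 9 fixed lists with another rab8d-2 effect in gun1-101 than in WT, each past the threshold of the interaction test with the preset correlation for the lists. For nac103-11 it was 2 genes and 13 fixed lists. With an estimated correlation no list passed in either interaction (lowest adjusted p = 0.392 and 0.247), and fry called 0 lists in each. For the gun1-101 interaction, 5 of 100 splits of the 12 libraries gave as many genes, the real one included, with a highest other count of 3825, so chance cannot be excluded for the count of 41. Splits that call this many genes point to a structure of the samples, since those with as many genes as the real split or more put rab8d-2 carriers unevenly in the groups. Among the 42 splits with the carriers placed evenly, the real one alone reached 41 and the highest other was 0. For the nac103-11 interaction, 7 of 100 splits gave at least 2 genes, with a highest other count of 6664, so chance cannot be excluded there either. Among its 52 even splits, the real one alone reached 2 and the highest other was 1. An even split can still hold carriers and non-carriers in the same group, which adds to the spread and lowers the count. The even splits therefore do not decide on chance in either interaction.

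Of 12 tested aliphatic glucosinolate genes, 6 were called with a higher rab8d-2 effect in gun1-101 than in WT, a pattern seen in the data and then tested on the same data. BCAT4, CYP79F1, CYP83A1, SOT17, SOT18 and FMO GS-OX1 were not called. The median log2 interaction of the 12 was 3.72 (mean 3.67 ± 0.51 SE over genes, which are not independent replicates). With an estimated correlation the group was not called (p = 0.0538 adjusted over the 6 added groups and 10 contrasts). With the clock score as a covariate the median was 3.443 and 1 of 12 genes was still called, so a linear effect of that score did not account for the pattern. The slope of the covariate comes from differences within genotypes, which were wide in WT (SD 6.11) and narrow in gun1-101 (SD 0.15). It therefore cannot decide on a difference in clock phase between genotypes, which stays open. The median SE per gene was 0.898 with the covariate against 0.809, and this was not separated from the lower median and the lost degree of freedom as reasons for the ended calls. A trend with transcript length is argued against by a median of 3.715 with that trend removed, where 7 of 12 were called. A candidate explanation is an effect of GUN1 on these genes that depends on RAB8D, which stays open beside growth conditions that could differ between lines, since the score was lowest in gun1-101 (0.93 ± 0.52) and highest in gun1-101 rab8d-2 (4.94 ± 0.17).

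Between the double mutants, many more genes were lower (765) than higher (270) in gun1-101 rab8d-2. A trend with transcript length in the libraries may account for it: with the trend removed 35 genes were called, 26 higher and 9 lower. Whether 1 library, nac103-11 rab8d-2 replicate 3, accounts for it stays open. Without it 21 genes were called, 16 higher and 5 lower. Without it and WT replicate 3 together 446 were called, 128 higher and 318 lower, so more genes were still lower there. The fall to 21 is not specific to that library, since 11 genes (9 higher, 2 lower) and 12 (9 higher, 3 lower) were called without gun1-101 rab8d-2 replicates 1 and 2. Replicate 3 of nac103-11 rab8d-2 had a Spearman correlation with exon length of -0.410, against 0.377 and 0.333 in the other libraries of its genotype, so these explanations are not separate. A difference between the mutations stays open. MRD1 was the 1 of 28 named genes whose call did not depend on a single library, and SOT18, AK3 and XPL1 lost their calls and not their folds in 3 refits (log2 1.77 to 1.91, 1.86 to 1.89 and -2.37 to -2.18).

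MRD1, at 19963047 to 19964712 on chromosome 1, was low in gun1-101 (0.831 CPM), rab8d-2 (0.393 CPM) and gun1-101 rab8d-2 (0.0392 CPM) and near the WT level of 64.3 ± 22.2 CPM in nac103-11 (53.7 CPM) and nac103-11 rab8d-2 (53.4 ± 15.5 CPM). That rab8d-2 lowers MRD1 whatever the line is argued against by the interaction of nac103-11 and rab8d-2, log2 7.325 ± 0.848. A stretch of chromosome that differs between the lines stays open as a candidate explanation. Between the double mutants, 1 of the 20 nearest tested genes, AT1G53440, within 83.2 kb, had an unadjusted p below 0.001, which alone is too few to tell. At 0.01 it was 7 of 20 (95% interval 15.4% to 59.2%) against 10.9% of all genes, and at 0.05 it was 8 of 20 (19.1% to 64.0%) against 24.6%. A state of this gene alone that was passed on in some lines, such as silencing, may be another candidate explanation and was not tested, since the table holds no measure of it.

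For the contrasts of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real count was 2585 against a highest other of 16 in rab8d-2 against WT, 4 against 0 in gun1-101 against WT, 2 against 0 in nac103-11 against WT, 878 against 1 in gun1-101 rab8d-2 against rab8d-2, and 1035 against 43 between the double mutants. It was 5946 against 0 in gun1-101 rab8d-2 against gun1-101 and 6086 against 2 in nac103-11 rab8d-2 against nac103-11. In each of these 7 contrasts 1 split, the real one, gave as many genes. In nac103-11 rab8d-2 against rab8d-2, 2 of the 10 splits gave at least 534 genes, the other one, with nac103-11 rab8d-2 replicate 3 set beside rab8d-2 replicates 1 and 3, giving 795. For both slopes and the shared genes, 1 of 100 splits of the libraries as given, the real one, gave as large a value. It was 0.919 against 0.709 for the slope in gun1-101, 0.911 against 0.689 for the slope in nac103-11, and 239 against 82 shared genes. Each split's slope was fitted to its 2585 genes of lowest p, the number called in the real one. For the slopes this cannot decide on chance, since the real split alone held all 6 rab8d-2 carriers in the groups labelled as carriers. The other splits mixed carriers with non-carriers, which lowers the rab8d-2 effect itself. For the count of shared genes, other splits can likewise hold libraries of different genotypes in the same group. That adds to the spread and lowers the count, so the splits do not decide on chance for the shared genes either. The real count also depended on the setting: it was 79 with gun1-101 rab8d-2 replicates 1 and 2 summed, 73 with a replicate block, 41 and 35 without rab8d-2 replicates 1 and 3, and 75 without gun1-101 rab8d-2 replicate 2. These lie below 82, and splits were not run under those settings. The splits do not show how many of the shared genes come from the shared rab8d-2 libraries, for which simulated lists of the same sizes gave 131.5.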

How the results depend on the processing

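Of the alternatives in this part, those that leave out WT replicate 3 and nac103-11 rab8d-2 replicate 3 together, sum gun1-101 rab8d-2 replicates 1 and 2, use a clock or seed storage covariate or remove a length trend were tests chosen after the data were seen. No named gene reversed its called direction. List tests were rerun only with an estimated correlation, fry, a replicate block and members matched by locus ID alone, and no list reversed its called direction there. An estimated correlation changes the p of camera and not its direction. Named genes kept their side of the threshold in 8190 values, lost it in 1148 and gained it in 163. With an estimated correlation 90 of 250 list tests lost their call, and with fry 51 lost and 8 gained one. With members matched by locus ID alone 4 lost and 7 gained a call, and with a replicate block 3 gained one. DESeq2 size factors and no filter on low counts kept all 10 gene counts within 1.5 times. The depth of the libraries left genotypes with a floor of 0.0387 to 0.0487 CPM. In simulations of rab8d-2 against WT, edgeR recovered 80% of 50 genes changed 4-fold and 10% of those changed 2-fold. The simulations changed few genes, which makes the adjusted threshold stricter than in the data. They set no limit for the data, where 1651 of the 2585 genes called in that contrast changed at least 2-fold and the others less. The cause was not tested for the values below, except where fewer genes, fewer libraries or a 2-fold minimum follow from the alternative itself.

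At 2-fold the counts were 1651 (rab8d-2 against WT), 3624 (nac103-11 rab8d-2 against nac103-11) and 473 (between the double mutants). The DESeq2 Wald test gave 4150, 78 and 58 for rab8d-2, gun1-101 and nac103-11 against WT, 2018 and 2096 for the gun1-101 and nac103-11 double mutants against rab8d-2, 448 and 548 for their interactions, 2611 between them, and 720 shared genes. With only the libraries of the contrast the counts were 76, 0 and 0 for rab8d-2, gun1-101 and nac103-11 against WT, 2 for nac103-11 rab8d-2 against rab8d-2, 10974 and 2875 for the double mutants against gun1-101 and nac103-11, 103 for the gun1-101 interaction and 2 between the double mutants. The counts of 0 had 1489 and 1363 genes at an unadjusted p below 0.05 in the fit of all libraries. On TPM they were 4 for nac103-11 against WT, 1337 for gun1-101 rab8d-2 against rab8d-2, and 284 and 58 for the interactions. With a replicate block they were 545 and 122 for the double mutants against rab8d-2, 18 for the gun1-101 interaction, 28 between the double mutants and 73 shared genes, where 16 of 45 same-number pairs of libraries correlated above 0.1, all 3 of gun1-101 with gun1-101 rab8d-2 among them.

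Without WT replicate 3 and nac103-11 rab8d-2 replicate 3 the counts were 7974, 3946 and 1219 for rab8d-2, gun1-101 and nac103-11 against WT, 3285 for gun1-101 rab8d-2 against rab8d-2, 9517 against gun1-101, 748 and 8 for the interactions and 446 between the double mutants, with a slope in gun1-101 of 0.732. With gun1-101 rab8d-2 replicates 1 and 2 summed they were 234 and 236 for the double mutants against rab8d-2, 3908 for gun1-101 rab8d-2 against gun1-101, 16 for the gun1-101 interaction, 12 between the double mutants and 79 shared genes. A clock covariate gave 1561 for gun1-101 rab8d-2 against rab8d-2, 20 and 10 for the interactions and 63 between the double mutants. Removing a length trend gave 7 for the nac103-11 interaction and 35 between the double mutants. A seed storage covariate gave 29 and 173 for gun1-101 and nac103-11 against WT, 1578 and 7258 for the double mutants against rab8d-2, 1477 and 34 for the interactions, 4138 between the double mutants and 1193 shared genes.

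Leaving out 1 library at a time gave 447 to 3602 genes in rab8d-2 against WT, 2 to 39 in gun1-101 against WT, 2 to 3 in nac103-11 against WT, 209 to 829 and 45 to 912 in the gun1-101 and nac103-11 double mutants against rab8d-2, 3849 to 4520 in gun1-101 rab8d-2 against gun1-101 and 4020 to 6879 in nac103-11 rab8d-2 against nac103-11. The interactions ranged from 11 to 116 and from 2 to 72 genes, the contrast between the double mutants from 11 to 1668, the shared genes from 35 to 334, and the slopes from 0.754 to 0.899 in gun1-101 and from 0.703 to 1.02 in nac103-11.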

Other observations

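Except for the values of replicates 1 and 2 of gun1-101 rab8d-2, the gene groups in this part, and the tests of them, were chosen after the data were seen.

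Aliphatic glucosinolate synthesis genes, which include the chain elongation enzyme gene MAM1 and the regulator gene MYB28, rose in 10 of 12 members in gun1-101 rab8d-2 against gun1-101 (median log2 4.13, adjusted p = 7.04e-12, and 0.442 with an estimated correlation). The sulfotransferase gene SOT18 was 1 of the 2 that did not pass (log2 0.20, adjusted p = 0.652). In gun1-101 against WT, edgeR called 0 of the 12 (median -2.19, camera adjusted p = 4.84e-16, and 0.314 with an estimated correlation). Against rab8d-2, 4 of 12 members were higher in gun1-101 rab8d-2 (median 1.83, adjusted p = 1.40e-10, and 0.442 with an estimated correlation). In nac103-11 rab8d-2 against rab8d-2, 1 member, SOT18, was lower, while the group was called at a median of 0.86 (adjusted p = 0.00947, and 0.952 with an estimated correlation). The group was also called in nac103-11 against WT (median 0.95, adjusted p = 0.0127, and 0.952 with an estimated correlation). Between the double mutants it was called too (median 0.99, adjusted p = 0.000934, and 0.952 with an estimated correlation). The interaction of gun1-101 and rab8d-2 gave 6 of 12 members (adjusted p = 1.87e-32, and 0.0538 with an estimated correlation), and that of nac103-11 and rab8d-2 gave 0 of 12 (adjusted p = 0.697). Group scores were 2.82 ± 0.51 log2 CPM in WT, 3.55 ± 0.85 in nac103-11, 3.00 ± 0.82 in rab8d-2 and 3.88 ± 0.75 in nac103-11 rab8d-2 (SD, n = 3).

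Clock genes differed between the libraries of WT, of rab8d-2 and of gun1-101 rab8d-2. The 4 evening genes PRR5, TOC1, ELF4 and LUX were called lower as a group in gun1-101 against WT (median -1.59, adjusted p = 0.000934, and 0.682 with an estimated correlation) with no member past the threshold, and higher in the gun1-101 interaction (median 2.04, adjusted p = 0.00119, and 0.682 with an estimated correlation). The 3 morning genes CCA1, LHY and PRR9 were not called in any contrast (adjusted p = 0.104 in gun1-101 against WT). The clock score was 2.43 in rab8d-2 replicate 3 and -7.62 and -7.01 in the other libraries of rab8d-2, and -1.14 in gun1-101 rab8d-2 replicate 3 against -6.29 and -6.64.

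Seed storage genes, which encode cruciferins and oleosins, were called lower as a group in nac103-11 against WT (median -4.82, adjusted p = 0.00531, and 0.753 with an estimated correlation) and in the gun1-101 interaction (median -5.30, adjusted p = 0.0166, and 0.952 with an estimated correlation), with none of 4 members past the threshold. Their scores were 3.12 ± 3.15 in WT, 3.09 ± 1.07 in gun1-101 and -1.38 ± 1.34 in nac103-11. The 6 heat shock genes were called lower in nac103-11 against WT (median -4.08, adjusted p = 0.000124, and 0.736 with an estimated correlation) with no member past the threshold, and their score was 9.40 in WT replicate 3 against 2.88 and 4.39 in the other WT libraries. The 6 early wound and touch genes were not called in any contrast (adjusted p = 0.124 in nac103-11 against WT).

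Replicates 1 and 2 of gun1-101 rab8d-2 differed less from each other than any other pair of replicates: the squared difference per gene over that of counting error was 2.14, where the other 17 pairs had 12.2 to 182, and the median absolute log2 difference was 0.0759. Both were kept, and the labels do not say whether they came from 1 RNA sample, in which case n is 2 for that genotype. QQS, at 12349047 to 12349933 on chromosome 3, had 17.8 ± 16.1 CPM in WT (0.592 in replicate 2), 12.8 in nac103-11 and 14.2 in nac103-11 rab8d-2, against 0.176 in gun1-101, 0.378 in rab8d-2 and 0.310 in gun1-101 rab8d-2. MRD1 was low in the same 3 mutants. AT4G29200, on chromosome 4, had 66.0 ± 35.1 CPM in WT and no more than 0.260 CPM in each other genotype.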
